A study of Panax japonicus with 15 samples.

How the data were processed

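RNA of pericarp, the fruit wall left after the seed is taken out, was sequenced from Panax japonicus, a ginseng relative used as a medicinal herb. Per the labels' protocols, the pericarp was dissected with a scalpel, frozen and ground, total RNA was extracted, and cDNA libraries were made from fragmented mRNA with random primers. There were 15 libraries, 3 from each of 5 fruit-colour periods that the labels call B, P, G, R and Y. The labels give no order of the periods, no control and no spelling-out of the letters, so the letters are used as they stand. The 3 libraries of a period are described in the protocol as biological replicates; the labels do not say how they relate to plants or days, so p-values measure the spread between these samples.

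The authors deposited 1 table of TPM values, per the table's name and its column sums; TPM is a unit that by definition divides reads by transcript length and scales each library to the same total. The table held 462117 features, and its columns summed to between 999997 and 1000003. All 15 sample columns matched a library by title. The identifiers have the form Cluster-number.number, and the features are called transcript clusters here; 388342 of them share the prefix 64249. The assembler, clustering step, aligner and quantifier are not given in the sources used here. The submitters' processing notes list the mouse builds GRCm38 and mm10, and no identifier in the table refers to a mouse gene. The table does not pair the identifiers with gene names, and no reference was used here, so the planned gene lists (chlorophyll synthesis and breakdown, photosynthesis, carotenoid, phenylpropanoid, flavonoid and anthocyanin, lignin, triterpene saponin, ethylene and abscisic acid, cell wall, seed, heat shock and other-organism lists) were not analysed here, and no function is given for any transcript cluster. Genome positions were likewise not analysed here.

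A transcript cluster was tested if its TPM was at least 1 in at least 3 libraries, which kept 138664. Values were transformed to log2(TPM + 1), so a difference on this scale understates the change of low transcript clusters. TPM keeps no read depth: the number of reads behind a value is unknown, and no counting interval or floor is given. TPM values are not counts, so no count model was used. One limma model (version 3.58.1, R 4.3.3) with the 5 period means was fitted to all 15 libraries, which leaves 10 residual degrees of freedom, with a variance prior that follows mean expression. The moderated F test asked whether the 5 periods differed, and the 10 contrasts compared every pair of periods. Each used Benjamini-Hochberg adjustment within its own test, and a transcript cluster was called at an adjusted p under 0.05. A transcript cluster was counted as highest, or lowest, in a period when all 4 contrasts with the other periods were called in that direction. Tables were also handled with Python 3.11.15, pandas 2.3.3 and NumPy 2.4.6.

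With no gene names, the rule for named transcript clusters takes for each period the 1 transcript cluster highest and the 1 lowest in it with the largest smallest-of-4 log2 difference, among those with a mean TPM of at least 10 in at least 1 period. Any other identifier printed was chosen after its values were seen.

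The model was tested on simulated data: 138664 transcript clusters with the real means and residual spread, of which 200 with a mean TPM of at least 10 were raised in the G libraries. For the G period against the B period, the test recovered 5 of 50 changed by 1 on the log2 scale, 35 of 50 changed by 2, 32 of 50 changed by 3 and 45 of 50 changed by 4, with 6 false calls. In this simulation, log2 changes near 1 were therefore mostly not called. The simulated noise was normal, with the same spread in all libraries for a given transcript cluster. The 200 changed ones were also far fewer than the 7949 called for G against B in the real data. The adjusted cutoff loosens as more change, so the share recovered in the real data may differ.

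The tests, the gene lists, the naming rule and the following alternatives were fixed before the data were examined. The alternatives were a pseudocount of 0.1, no filter beyond a value above 0 in 1 library, a filter on a mean TPM of at least 10, rescaling by the median ratio over the 33508 transcript clusters above 0 in all 15 libraries, the replicate number as a block, no variance trend, a fit on the 6 libraries of each pair alone, adjustment over all 10 contrasts together, and leaving out each library in turn. Library weights, a fit without the P libraries and a filter on values above 0 in all 15 libraries were added after seeing the data. No 2 libraries held identical values.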

Results

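The study asked how gene expression in the fruit wall of Panax japonicus differs between 5 periods of fruit colour, each sampled as 3 libraries. The number of transcript clusters above 0 TPM ranged from 97466 in P replicate 1 to 187300 in P replicate 3. Its mean was 168123 ± 7461 (SD, n = 3) in the B period, 138396 ± 45445 (SD, n = 3) in P, 158045 ± 13301 (SD, n = 3) in G, 173750 ± 4342 (SD, n = 3) in R and 172196 ± 13157 (SD, n = 3) in Y. The tested transcript clusters held 91.9% ± 0.17 (SD, n = 3) of TPM in the R libraries and 92.0% ± 0.59 (SD, n = 3) in the Y libraries. They held 85.9% ± 3.98 in B, 86.3% ± 3.38 in G and 73.4% ± 5.18 in P (each SD, n = 3). Each of the 3 P libraries lay below each of the other 12 in this share. Read depth is unknown, since TPM keeps none.

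Period means correlated best between R and Y, and least between G and each of B and P. Across the tested transcript clusters, which are not independent replicates, the Pearson correlation of period means on the log2(TPM + 1) scale was 0.874 between R and Y. It was 0.848 between G and Y, 0.830 between B and R, and 0.818 between B and P. The lowest values were 0.742 between B and G and 0.748 between P and G; over pairs of single libraries the order of these was the other way, with a mean of 0.591 ± 0.023 between B and G and 0.586 ± 0.055 between P and G (SD over 9 pairs each). Single libraries correlated at a mean of 0.775 ± 0.012 within Y, 0.759 ± 0.010 within R, 0.706 ± 0.022 within G, 0.684 ± 0.017 within B and 0.641 ± 0.029 within P (SD over 3 pairs of libraries each). Between single libraries the mean was 0.738 for R and Y, 0.635 for B and P, and 0.641 for P and R, the same as within P. A wide spread within a period lowers its correlations with the others. The ranking of periods as a whole therefore cannot be told apart from that spread and is not a measure of similarity alone. For 1 part of it the values go against the spread. B correlated lower with G than with P, although G correlated higher within itself than P did. This argues against spread as the whole reason there. The ranges of single pairs overlapped, from 0.566 to 0.635 for B and G and from 0.580 to 0.713 for B and P. For 12 of the 15 libraries the best-correlated library came from the same period. The exceptions were B replicate 1, closest to R replicate 3 at 0.714, P replicate 3, closest to B replicate 1 at 0.713, and G replicate 2, closest to Y replicate 1 at 0.721.

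**Figure D1:**
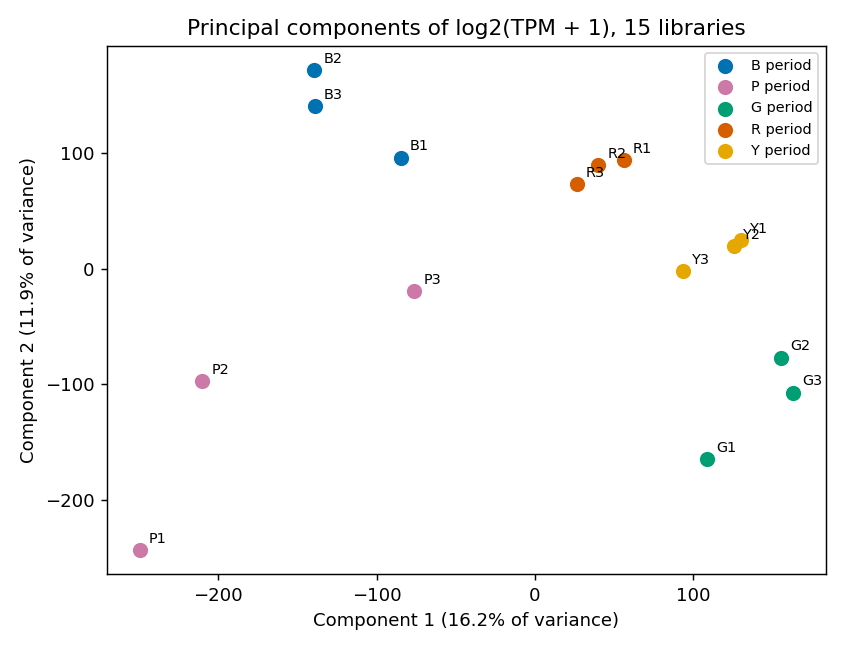
Each point is 1 library, coloured by period, on the first principal component of log2(TPM + 1) over the tested transcript clusters (horizontal, 16.2% of variance) and the second (vertical, 11.9% of variance); the axes have no unit. The 3 R libraries lie close together, as do the 3 Y libraries, the G libraries lie at the lower right, and the 3 P libraries are spread from the lower left toward the centre.

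Expression differed among the 5 periods for 10313 of 138664 transcript clusters, or 7.44% (limma moderated F test, Benjamini-Hochberg adjusted p under 0.05). Of these, 6207 differed by at least 4-fold between the highest and lowest period mean, and 828 by at least 16-fold, on the log2(TPM + 1) scale. Abundant transcript clusters were called far more often than rare ones. The log2(TPM + 1) scale understates changes of low values, so these shares do not show that abundant ones changed more often. Among the 960 with a mean TPM of at least 100, which together held 23.4% of all TPM on average, 533 were called, or 55.5%. The share was 24.5% of 14560 with a mean TPM from 10 to 100, 6.87% of 71863 from 1 to 10, and 2.49% of 51281 under 1. In each library the called transcript clusters held between 20.1% and 31.9% of TPM.

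**Figure D2:**
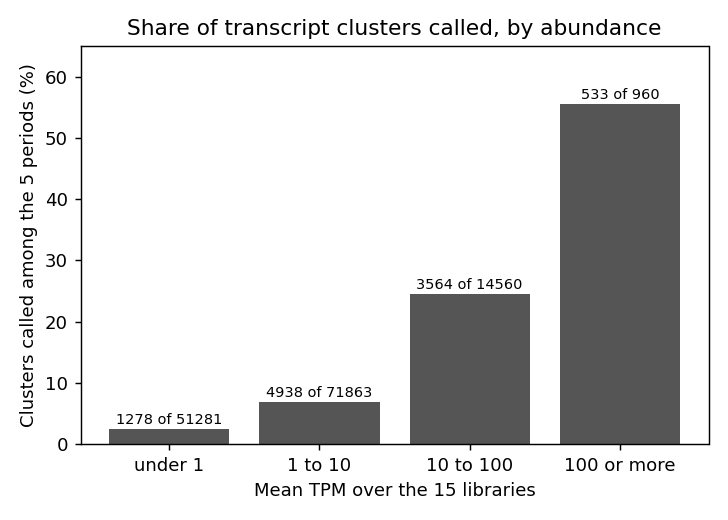
Bars give the percentage of tested transcript clusters called among the 5 periods (vertical axis, from 0) in 4 classes of mean TPM over the 15 libraries (horizontal axis); the numbers printed over the bars are those called and tested. The called share is 2.49% in the lowest class and 55.5% in the highest.

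The most frequent single pattern among the called transcript clusters was higher expression in G, R and Y than in B and P. When the 5 period means of each called transcript cluster were divided at their largest gap, G, R and Y lay above B and P for 1879, or 18.2%. G alone lay above the gap for 1291, or 12.5%, and G alone lay below it for 974, or 9.44%. B alone lay above it for 768, or 7.45%. P alone lay below it for 981, or 9.51%, but for 492, or 5.22%, with median-ratio scaling. P alone lay above it for 425, or 4.12%, and for 695, or 7.38%, with median-ratio scaling. These shares describe the called transcript clusters and carry no test of their own.

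The comparisons of the G period with B and with P called the most transcript clusters, and the comparison of Y with R the fewest. Against B, the G period had 3733 higher and 4216 lower transcript clusters, 7949 in all, and this balance turned with median-ratio scaling, where 53.8% were higher against 47.0% on the TPM as deposited (limma, adjusted p under 0.05). Against P it had 5088 higher and 2396 lower, 7484 in all, or 68.0% higher, and 59.0% with median-ratio scaling. Y against R gave 149 higher and 152 lower, 301 in all. The difference was at least 2-fold on the log2(TPM + 1) scale for 7630 of the G against B calls, 7094 of the G against P calls and 299 of the Y against R calls. Among the 960 transcript clusters with a mean TPM of at least 100, G had 226 higher and 166 lower than B, and 266 higher and 149 lower than P. With median-ratio scaling these were 250 and 154, and 211 and 175. The balance of G against B thus also turned with abundance on the TPM as deposited. It was 1392 higher and 1231 lower from 10 to 100 TPM, 1595 and 2262 from 1 to 10, and 520 and 557 under 1.

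The order of these counts held under most settings. Over the 26 that gave all 10 counts, the main one included, the 2 G comparisons ranked highest in 21. Without G replicate 2, the G period against P period count of 5312 fell below the Y period against P period count of 5395, and without G replicate 3 the same counts were 5616 and 5768. The order also changed with library weights, with fits on 6 libraries alone and with a mean TPM of at least 10. Y against R ranked lowest in 24. The P period against B period count was lower in the others, at 414 against 914 for Y period against R period with library weights, and at 18 against 70 in the fits on 6 libraries. No leave-out moved either G count by over 1.5 times. The Y against R count moved by more than that in 6 of 15 leave-outs, being 198, 187 and 199 without R replicates 1, 2 and 3, and 188, 184 and 188 without Y replicates 1, 2 and 3.

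Y and R each had more transcript clusters higher than lower when set against B and against G, over all called ones. This did not hold for Y against G with median-ratio scaling, where 49.2% were higher. With a mean TPM under 1, more were lower than higher in each of these comparisons. Y against B had 2567 higher and 1805 lower, 4372 in all, and R against B had 1438 higher and 576 lower, 2014 in all (limma, adjusted p under 0.05). R against G had 1893 higher and 1297 lower, 3190 in all, and Y against G had 953 higher and 727 lower, 1680 in all. Among the 960 transcript clusters with a mean TPM of at least 100, R against B gave 157 higher and 12 lower, R against G 175 and 44, Y against G 99 and 17, and Y against B 213 and 69. Y against R gave 1 higher and 15 lower in that class. Among those with a mean TPM under 1, R against B gave 123 higher and 155 lower, and Y against B 240 and 323. R against G gave 168 higher and 319 lower there, and Y against G 136 and 234. With median-ratio scaling, R against G was 50.4% higher over all called transcript clusters, against 59.3% on the TPM as deposited. Leaving out 1 library moved R against B by over 1.5 times without R replicates 1, 2 and 3 (1040, 1064 and 1182) and B replicates 2 and 3 (1159 and 1238). It moved Y against B without Y replicates 1, 2 and 3 (2310, 2396 and 2769) and B replicates 2 and 3 (2571 and 2692). R against G fell to 1833, 1758 and 2008 without R replicates 1, 2 and 3, and Y against G to 1029, 1022 and 1005 without Y replicates 1, 2 and 3.

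In each comparison with the P period most called transcript clusters were lower in P on the TPM as deposited, while with median-ratio scaling P and B were even. R against P had 3177 higher and 684 lower transcript clusters, 3861 in all, so that 82.3% were higher in R. Y against P had 4572 higher and 1317 lower, 5889 in all, with 77.6% higher in Y. P against B had 293 higher and 706 lower, 999 in all, with 29.3% higher in P. Median-ratio scaling moved the median log2 difference over all tested transcript clusters by -0.15 for R against P, by -0.14 for Y against P and by 0.14 for P against B. With it the shares became 66.3% for R against P, 61.5% for Y against P and 50.1% for P against B. In the class with a mean TPM of at least 100, R against P gave 241 higher and 19 lower, and 149 and 39 with median-ratio scaling. P against B gave 26 higher and 24 lower in that class, and 41 and 5 with median-ratio scaling. The P against B count changed by over 1.5 times in 8 of 15 leave-outs. It was 2589 without P replicate 3, 1679 without B replicate 1, 630 and 593 without P replicates 1 and 2, 470 and 498 without B replicates 2 and 3, and 654 and 648 without Y replicates 1 and 2. R against P fell to 1847, 1914 and 2229 without R replicates 1, 2 and 3 and to 2479 without P replicate 1. Y against P fell to 3062, 3131 and 3869 without Y replicates 1, 2 and 3 and to 3924 without P replicate 1.

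**Figure D3:**
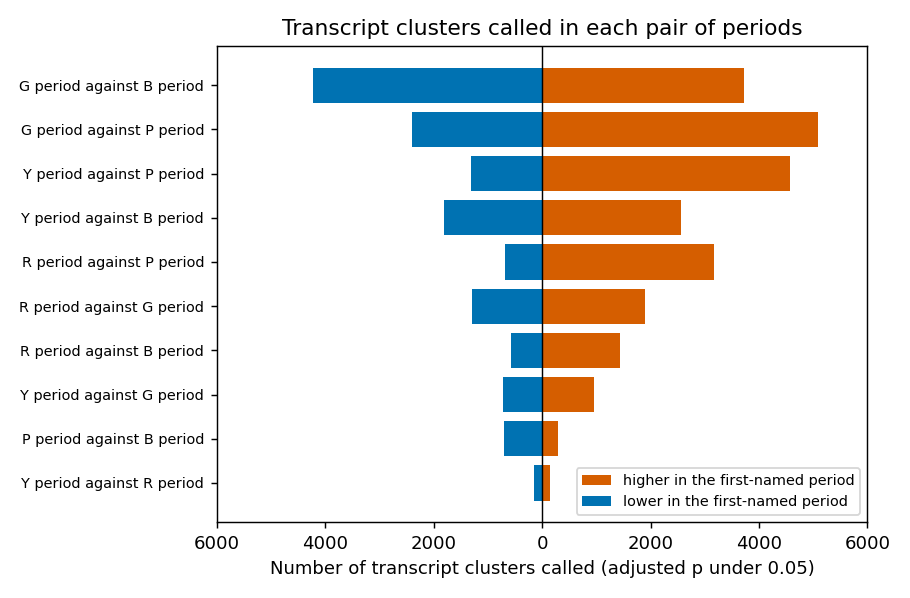
Bars give the number of transcript clusters called in each pair of periods (limma, adjusted p under 0.05), to the right where the first-named period was higher and to the left where it was lower. G against B and G against P have 7949 and 7484 calls, and Y against R has 301.

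The G period was set apart from each of the other 4 periods by more transcript clusters than any other period was. In G, 542 transcript clusters were higher than in all 4 other periods and 322 were lower; 530 and 302 of these differed by at least 2-fold in all 4 contrasts. The 542 held 2.21% of TPM in the G libraries. Which of the features highest in the G period and features lowest in the G period were more numerous turned with a pseudocount of 0.1 (290 and 386), a mean TPM of at least 10 (229 and 401) and values above 0 in all 15 libraries (294 and 434). B had 179 highest and 28 lowest, P had 148 and 115, R had 75 and 2, and Y had 110 and 4. The balance of features highest in the P period and features lowest in the P period turned under the same 3 settings (77 and 189, 69 and 240, and 92 and 213) and without P replicate 3. It turned under the last 2 for B (36 and 55, and 47 and 50) and under the last for R and Y (3 and 4 in each). G had the most transcript clusters highest in it under all 24 settings that gave these counts, the main one included, and the most lowest in it under 23. Without P replicate 3, P had 711 lowest and 358 highest. G had 347 highest and 213 lowest without Y replicate 2, and 208 lowest without Y replicate 3.

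Single libraries also moved the other sets by over 1.5 times. B had 364 highest and 75 lowest without B replicate 1. The B lowest count was 13 without B replicate 2 or 3, 17 without P replicate 2 or R replicate 1, 16 without R replicate 2 and 18 without Y replicate 2. P had 78 and 79 highest without B replicates 2 and 3. The P lowest count was 46 and 54 without B replicates 2 and 3, 56 without P replicate 1, 61 without R replicate 1 or 2 and 64 without Y replicate 1 or 2. R had 45, 42 and 39 highest without Y replicates 1, 2 and 3, and Y had 73 highest without R replicate 2. The 2 lowest in R became 0 without B replicate 3 or R replicate 1 or 3, and 1 without B replicate 1 or 2, P replicate 3, G replicate 3, R replicate 2 or any Y library. The 4 lowest in Y became 1 without G replicate 1, R replicate 2 or Y replicate 2, and 2 without R replicate 3.

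Some of the transcript clusters that marked a period were listed at 0 in all other libraries. Cluster-64249.280307 stood at 194 ± 21.8 TPM (SD, n = 3) in the B period and was listed at 0 in the 12 other libraries (largest adjusted p of the 4 limma contrasts 3.92e-08). Cluster-64249.370955 stood at 65.9 ± 49.5 TPM (SD, n = 3) in R and Cluster-64249.386907 at 81.5 ± 60.0 TPM (SD, n = 3) in Y, each listed at 0 elsewhere (largest adjusted p 7.26e-05 and 0.000281, limma). Cluster-64249.133091 stood at 82.3 ± 62.7 TPM (SD, n = 3) in G, at a mean of 0.287 in Y and at 0 in B, P and R (largest adjusted p 3.29e-05, limma). The limma p-values here use a spread pooled over all periods, to which a period listed at 0 throughout adds none. They therefore do not measure the spread within the expressing period alone. In R replicates 1, 2 and 3, Cluster-64249.370955 stood at 45.6, 29.8 and 122 TPM. In Y replicates 1, 2 and 3, Cluster-64249.386907 stood at 83.9, 20.3 and 140 TPM. Cluster-64249.104926, the one named for P, was far more uneven: 12.6, 224 and 1707 TPM in P replicates 1, 2 and 3, against means of 0.480 in B, 0.117 in Y and 0 in G and R (largest adjusted p 0.0153, limma). The alternatives left Cluster-64249.104926 highest in the P period with a largest adjusted p from 0.000173 to 0.0525, the latter without P replicate 2 and the only one over 0.05 (limma). Cluster-64249.104926 is also among the abundant transcript clusters of P replicate 3 that are flagged for a closer look below. There, 1 RNA source in P replicate 3 is left open, so Cluster-64249.104926 may not mark the P period as a whole.

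The opposite pattern was a transcript cluster listed at 0, or lowest, in 1 period and expressed in the others. Cluster-64249.72467 was listed at 0 in the 3 B libraries and had means from 53.8 TPM in R to 92.3 TPM in P (largest adjusted p 0.00013, limma). Cluster-64249.209477 was listed at 0 in the 3 G libraries and had means from 68.8 TPM in Y to 295 TPM in P (largest adjusted p 0.00147, limma). Cluster-64249.131965 averaged 3.59 ± 6.22 TPM in P and 148 ± 23.6 TPM in R (SD, n = 3 each). Its smallest log2(TPM + 1) difference from another period was -4.84 ± 0.79 (SE; largest adjusted p 0.0112, limma). Cluster-64249.148786 was listed at 0 in the 3 Y libraries and had means from 6.08 TPM in G to 12.3 TPM in P (largest adjusted p 0.00414, limma). Cluster-64249.187677 was lowest in R, at 2.38 ± 0.61 TPM, against 8.38 ± 1.18 in B and 28.4 ± 12.4 in G (SD, n = 3 each; smallest difference -1.48 ± 0.31 SE, largest adjusted p 0.0286, limma). The alternatives gave Cluster-64249.187677 lowest in the R period a largest adjusted p from 0.00488 to 0.129 (limma). The call was lost without B replicates 1, 2 and 3 (0.0691, 0.0947 and 0.0619), without R replicates 1, 2 and 3 (0.129, 0.0629 and 0.0835), with no filter (0.0924) and with no variance trend (0.0521). The other members of the small sets, whose names were taken after their values were seen, were Cluster-64249.129870 for R, at a mean of 4.23 TPM there against 13.4 to 20.3 elsewhere, and Cluster-64249.121734, Cluster-64249.134040 and Cluster-64249.141699 for Y, at means of 1.41, 7.11 and 0.663 TPM.

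**Figure D4:**
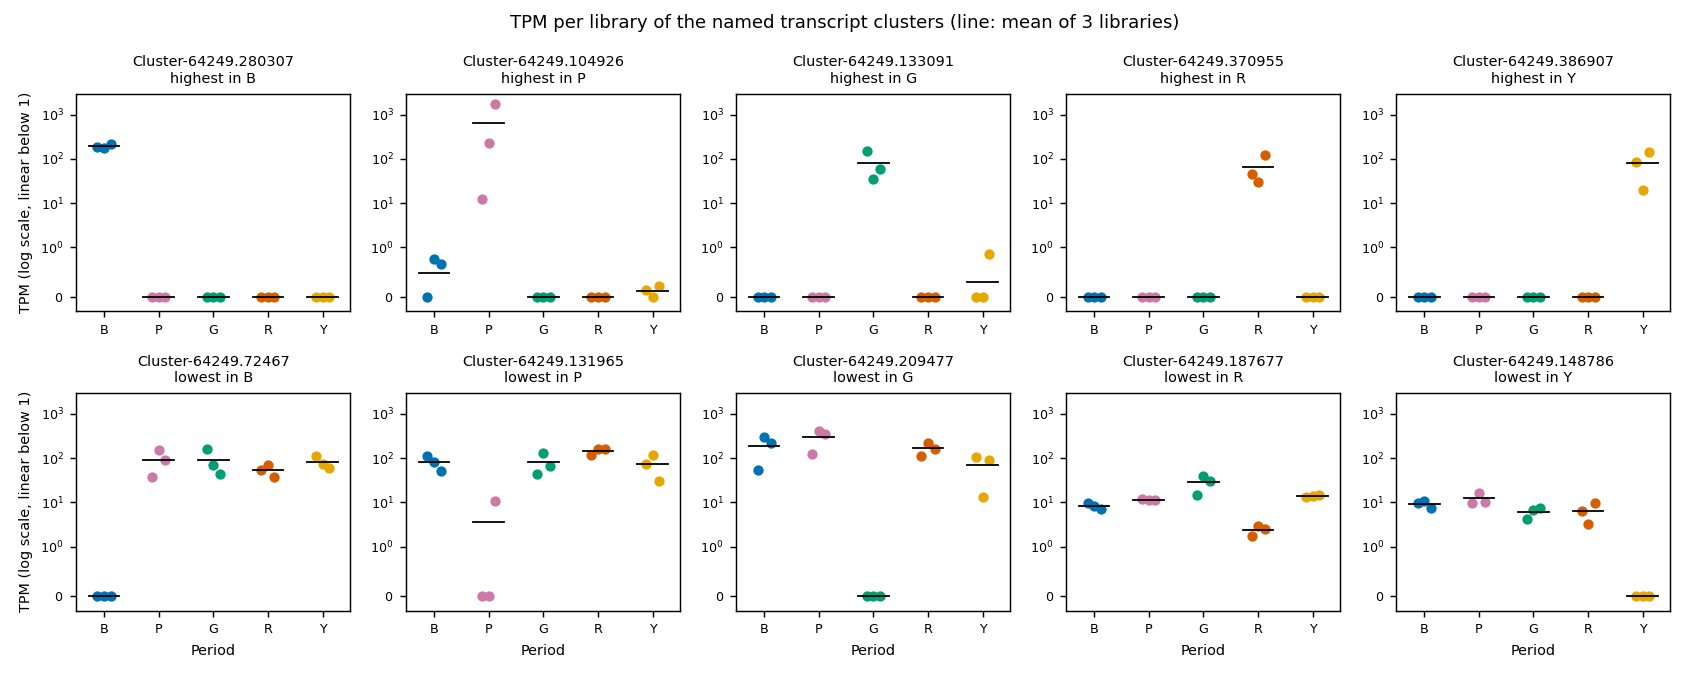
Each panel shows 1 named transcript cluster, with TPM per library on the vertical axis (log scale, linear below 1) and the 5 periods on the horizontal axis; points are libraries and lines are means of 3. The upper panels show the transcript clusters highest in B, P, G, R and Y, and the lower panels those lowest in the same periods; Cluster-64249.104926 ranges from 12.6 to 1707 TPM among the P libraries.

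Presence in 1 period alone was counted over the whole table, without the filter. Transcript clusters at 1 TPM or more in all 3 libraries of a period and listed at 0 in the 12 others numbered 110 for G, 81 for Y, 65 for B, 47 for R and 30 for P. In 100 random regroupings of the libraries, the 495 groups of 3 that did not match a period had a median of 23 and at most 65. The numbers for G and Y lay above that highest value and the number for B equalled it. In the other direction, 28 were listed at 0 in all P libraries and at 1 TPM or more in the 12 others. The numbers were 17 for G, 3 for B, 3 for Y and 0 for R. The random groups had a median of 1 and at most 56, so no period lay above their highest value.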

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

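The tests on P replicate 3, with their limits of 100 and 500 TPM, and the test of lower depth in P replicates 1 and 2 were chosen after the result was seen. Each result here was picked out as a signal in transcript clusters above 0 in a single library. The report's comparisons left those out, and the alternative with no filter included them. The 4817 and the 269 below follow other rules, and 502 of the 4817 were above 0 in P replicate 2. At least Cluster-64249.104926, which is among the 269, entered the comparisons.

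P replicate 3 held 17182 transcript clusters that were above 0 in no other library, against 3149 to 6583 in each of the other 14, and 4817 at 5 TPM or more and over 20 times every other library made up 15.1% of its TPM, by the same definition less than the 24.6% in P replicate 1 and 17.5% in P replicate 2. For the most abundant alone, deeper sequencing is argued against: 40 of the 4817 reached 500 TPM or more, and the highest number in any other library was 9. For the rest it stays open, since the 4817 had a median of 9.88 TPM, the lowest of the 15 libraries (the next was 11.2), and 433 reached 50 TPM, against 1597 in P replicate 1. Of 269 at 100 TPM or more and over 20 times every library but P replicate 2, chosen without it so that the choice does not limit the ratio, 61.3% were above 0 in P replicate 2, at a median of 2.75% of the level in P replicate 3; the interquartile range of the log2 ratio, over those above 0 alone, was 1.28, close to the 1.33 and 1.53 in B replicate 1 and P replicate 1, where 39.8% and 15.7% of 236 chosen the same way were above 0. The share above 0, more than the spread, is consistent with 1 RNA source that may reach P replicate 2 at a low level, while low expression of the same transcript clusters in P replicate 2 itself was not tested and stays open.

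P replicates 1 and 2 placed 24.6% and 17.8% of their TPM in transcript clusters above 0 in that library alone, against 2.41% to 11.3% in the other 13. Raised values of short transcript clusters through length normalization cannot be told apart from other causes: the log2 ratio of P replicate 1 to the lowest R or Y value differed by -1.53 between the upper and the lower 25% of those values, but it fell in all 15 libraries, since the values that divide it also order it, and lengths are not known here. Over 98546 transcript clusters above 0 in 1 of the 3 Y libraries, P replicate 1 lay above the R libraries by 1.55 on the log2 scale in the lower 25% and by 1.35 in the upper 25%, a difference of -0.21, and 13.5% were above 0, against 30.0% to 32.6% in the R libraries. Lower depth would give such an even shift and may account for part of the pattern. Whether it accounts for all of it cannot be told apart from other causes, because the median of the transcript clusters in P replicate 1 alone was 9.51 times that in the R libraries, or 3.73 times beyond the shift.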

How the results depend on the processing

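The library weights, the fit without the P libraries and the filter on values above 0 in all 15 libraries were chosen after seeing the data. The cause of the changes below was not tested, except where fewer transcript clusters or libraries entered by construction. Features are transcript clusters here. Read depth is unknown, so what it limits among low values cannot be given. With a pseudocount of 0.1, the counts beyond 1.5 times were 83 for features highest in the B period, 77 for features highest in the P period, 189 for features lowest in the P period, 290 for features highest in the G period and 8 for features lowest in the Y period. With no filter on low values, the counts beyond 1.5 times were 6216 for differences among the 5 periods, 284 for P period against B period, 4975 for G period against B period, 1128 for R period against B period, 2494 for Y period against B period, 4690 for G period against P period and 1967 for R period against P period. The same setting gave 3268 for Y period against P period, 1841 for R period against G period, 985 for Y period against G period, 132 for Y period against R period, 71 for features highest in the B period, 6 for features lowest in the B period and 64 for features highest in the P period. It also gave 30 for features lowest in the P period, 344 for features highest in the G period, 197 for features lowest in the G period, 33 for features highest in the R period, 0 for features lowest in the R period, 54 for features highest in the Y period and 1 for features lowest in the Y period. With a mean TPM of at least 10, the counts beyond 1.5 times were 5969 for differences among the 5 periods, 4239 for G period against B period, 2890 for Y period against B period, 4723 for G period against P period, 131 for Y period against R period and 36 for features highest in the B period. The same setting gave 55 for features lowest in the B period, 69 for features highest in the P period, 240 for features lowest in the P period, 229 for features highest in the G period, 5 for features highest in the R period and 6 for features highest in the Y period. With median-ratio scaling, the counts beyond 1.5 times were 53 for features lowest in the B period, 54 for features lowest in the P period and 1 for features lowest in the R period. With no variance trend, the counts beyond 1.5 times were 11 for features lowest in the B period, 65 for features lowest in the P period and 0 for features lowest in the R period. In fits on the 6 libraries of each pair alone, the counts beyond 1.5 times were 18 for P period against B period, 2365 for G period against B period, 616 for R period against B period, 1889 for Y period against B period and 948 for G period against P period. The same setting gave 832 for R period against P period, 1254 for Y period against P period, 1447 for R period against G period, 264 for Y period against G period and 70 for Y period against R period. With adjustment over all 10 contrasts together, the counts beyond 1.5 times were 1975 for P period against B period and 896 for Y period against R period. With library weights, the counts beyond 1.5 times were 414 for P period against B period, 914 for Y period against R period, 16 for features lowest in the B period, 43 for features lowest in the P period, 122 for features highest in the R period and 10 for features lowest in the Y period. With only values above 0 in all 15 libraries, the counts beyond 1.5 times were 109 for Y period against R period, 47 for features highest in the B period, 50 for features lowest in the B period and 92 for features highest in the P period. The same setting gave 213 for features lowest in the P period, 294 for features highest in the G period, 3 for features highest in the R period, 4 for features lowest in the R period and 3 for features highest in the Y period.

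The libraries share only a replicate number: of 30 correlations between same-numbered libraries of different periods, over deviations from the period means, 0 were over 0.1, with a range from -0.0615 to 0.0769, and 7 of 15 libraries correlated best with their own number. With the replicate number as a block, 13 of the 21 counts stayed within 1.5 times and the counts beyond it were 549 for P period against B period, 174 for Y period against R period, 13 for features lowest in the B period, 57 for features lowest in the P period, 40 for features highest in the R period, 1 for features lowest in the R period, 73 for features highest in the Y period and 1 for features lowest in the Y period. Without the 3 P libraries, all 6 counts that could be made stayed within 1.5 times. Leaving out 1 library at a time, the counts that left the 1.5-fold range ran from 470 to 2589 for P period against B period, 1040 to 2658 for R period against B period, 2310 to 5381 for Y period against B period, 1847 to 5619 for R period against P period, 3062 to 8029 for Y period against P period and 1758 to 3689 for R period against G period. Others ran from 1005 to 1838 for Y period against G period, 184 to 367 for Y period against R period, 120 to 364 for features highest in the B period, 13 to 75 for features lowest in the B period, 78 to 358 for features highest in the P period and 46 to 711 for features lowest in the P period. The last ran from 347 to 548 for features highest in the G period, 208 to 342 for features lowest in the G period, 39 to 79 for features highest in the R period, 0 to 3 for features lowest in the R period, 73 to 124 for features highest in the Y period and 1 to 5 for features lowest in the Y period. Those that stayed within it ran from 7942 to 11916 for differences among the 5 periods, 5375 to 9086 for G period against B period and 5312 to 9408 for G period against P period. None of the 10 named transcript clusters changed sign under any alternative that tested it, and 8 kept their calls in all of these. For those listed at 0 throughout their own period, or in all other libraries, the sign could not change. All 10 were chosen for large differences in the same data, so the kept signs and calls are no independent support.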

Other observations

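The identifiers in this part were picked after their values were seen; for B replicate 1, the positions towards P, G and Y were also chosen after the result was seen. The single most abundant value in the table was that of Cluster-64249.114148 in the G period, with a mean of 6646 ± 237 TPM (SD, n = 3). Its means were 1613 ± 196 in Y, 961 ± 219 in R, 461 ± 477 in P and 440 ± 260 in B (SD, n = 3 each). The log2(TPM + 1) difference of G from the other periods ran from 2.05 to 4.36 with an SE of 0.53, and the largest of the 4 adjusted p was 0.1 (limma), so it is not among the transcript clusters counted as highest in G.

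A pair of abundant transcript clusters varied widely among the libraries of 1 period. Cluster-64249.124918 stood at 50.9, 3353 and 2562 TPM in B replicates 1, 2 and 3, and at 1917, 1257 and 166 in R replicates 1, 2 and 3. Cluster-64249.132825 stood at 59.2, 2433 and 2728 TPM in the same B libraries and at 1163, 673 and 106 in the same R libraries. In the 8 libraries where the second was at 50 TPM or more, the ratio of the first to the second lay between 0.655 and 1.87. Means in P were 0.923 and 5.48 TPM.

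B replicate 1 correlated best with an R library, but it also correlated higher than B replicates 2 and 3 did with all 12 libraries of the other periods. A mislabelled R library is argued against: over the 2658 transcript clusters called between R and B without this library, its median position from the R mean, taken as 0, to the mean of the other B libraries, taken as 1, was 0.593 (quartiles 0.259 and 0.851). Placed the same way with themselves left out, B replicates 2 and 3 both had a median position of 1 and the R libraries lay between 0.0255 and 0.0484, with upper quartiles of at most 0.251. For B replicates 2 and 3, B replicate 1 helped to set both the calls (1159 and 1238) and the B mean. That may raise their positions, so the gaps that follow are not like for like. The position of B replicate 1 was below the lower of the other B libraries by 0.407 towards R, and by 0.359, 0.346 and 0.171 when placed the same way towards P, Y and G. Tissue nearer to R in particular therefore cannot be told apart from a library that is nearer to the other periods in general, and a mixture of material was not tested.

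The period labels were compared with other groupings of the 15 libraries, in 100 splits into 5 groups of 3, the real one included. For the differences among the periods, 1 of 100 splits gave as many calls, the real count being 10313 and the highest other 1536. That split was the real one, and 1 of 100 is the smallest share that these splits can give. Within that limit, the counts argue against a random grouping of the libraries. Of the other splits, 7 happened to contain a whole period, and without these the highest other was 405. The other splits gave a median of 72 calls, and 0 of them gave no call. As the groups of a random split have no names, the largest of its 5 counts was compared for the transcript clusters highest or lowest in a period. The highest other splits had 354 highest and 181 lowest, and 53 and 11 among those that contain no whole period. For G, with 542 highest and 322 lowest, 1 of 100 splits reached each count. The 179, 148, 75 and 110 highest in B, P, R and Y were each reached in 4 of 100 splits. So were the 28 and 115 lowest in B and P. All of these, and both G counts, lay above every split that contains no whole period. The 2 lowest in R, which 22 of 100 splits reached, and the 4 lowest in Y, which 13 reached, did not. Random splits mix periods that differ, which widens the spread, so these shares bear on the labels as a whole. They do not exclude chance for any 1 set on its own.

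Each pair of periods allows only 10 splits of its 6 libraries, too few for a share under 0.05; the smallest share is 1 of 10. The real counts and the highest of the other 9 splits were 7949 and 94 for G against B, 7484 and 110 for G against P, 5889 and 41 for Y against P, 4372 and 92 for Y against B, and 3861 and 63 for R against P. They were 3190 and 50 for R against G, 2014 and 137 for R against B, 1680 and 120 for Y against G, 999 and 147 for P against B, and 301 and 101 for Y against R.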
